A study of Eonycteris spelaea and Mus musculus with 51 samples.

How the data were processed

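Bulk RNA sequencing was carried out on blood, lung and muscle of the cave nectar bat Eonycteris spelaea and of the mouse, Mus musculus. Per the labels, control animals were sampled at baseline, heat animals right after 1 h of heat shock given to the living animal, and recovery animals after 1 h of heat shock and 4 h of recovery. The 51 libraries (27 bat, 24 mouse) fall into 18 groups of species, tissue and condition, with 3 libraries per group and 2 per group in mouse blood. The mouse blood libraries are numbered 1 and 3 in control and 1 and 2 in heat and recovery. Total RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra Directional kit, per the labels' protocols.

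The deposited values are raw read counts per gene, with 1 column per library, and hold no normalization by the authors. Per the submitters' processing notes, reads were aligned with STAR 2.7 and counted with featureCounts, whose version is not given in the sources used here. Those notes list the mouse build GRCm39 for every sample, the bat samples included, and give no bat assembly or annotation. Neither the strand setting of the counting nor any filter is stated, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The mouse table has 40840 rows named by gene symbol. The bat table has 30017 rows, of which 18152 carry human Ensembl gene identifiers, 762 mouse Ensembl gene identifiers, 10328 numbers of non-coding RNAs and 564 antisense names. The files do not pair the human identifiers with gene names, so bat genes are given by identifier and the gene lists below were tested in the mouse alone. Mouse identifiers in the bat table were given symbols from a mouse reference annotation (758 of 762), and 644 symbols occurred once in each table.

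Total counts per library ranged from 9.29 to 33.3 M in the bat and from 17.1 to 54.5 M in the mouse. The spread between animals, as the common biological coefficient of variation, was 0.536 in bat blood, 0.343 in bat lung, 0.295 in bat muscle, 0.263 in mouse blood, 0.161 in mouse lung and 0.338 in mouse muscle. Within each group of species, tissue and condition no library was a copy of another: for each such pair, the squared differences in counts of genes with at least 20 reads exceeded counting error, by a factor of 10.6 or more. Levels are given as edgeR CPM, counts scaled by library size and by the trimmed mean of M values (TMM), as mean ± SD over libraries.

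Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Each species and tissue was fitted alone over all of its libraries. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the robust quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05, and "rose" and "fell" are used for called genes. Heat and recovery were each compared with control, so these comparisons share their control libraries. Recovery was also compared with heat for the listed genes. The species difference was the bat change minus the mouse change, tested in a joint edgeR fit of the genes with a shared symbol that passed the filter in both species (57 in blood, 76 in lung, 45 in muscle).

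Before the data were examined, 26 gene lists were fixed. They cover heat shock proteins and co-chaperones, endoplasmic reticulum stress, mitochondrial chaperones and chaperonin, immediate early genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, glucocorticoid-responsive genes, oxidative stress, hypoxia and glycolysis, oxidative phosphorylation, proteasome subunits, cytosolic ribosomal proteins, the circadian clock, and p53 targets and apoptosis. Marker lists cover neutrophils, B cells, T and NK cells, monocytes and macrophages, erythroid cells, platelets, lung epithelium, endothelium, fibroblasts and matrix, adipocytes, and fast and slow muscle fibres. Lists with at least 5 tested members were tested against the other genes with camera (preset correlation 0.01, adjusted over all lists and comparisons). Camera with an estimated correlation, and fry, which tests whether a list moves 1 way on balance without comparing it with other genes, were run beside it. List members were counted over all genes tested and adjusted over the list alone.

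The genes named were also set beforehand: per comparison, the 5 genes that rose most and the 5 that fell most among called genes with a symbol, a mean of at least 5 CPM and no overlap between the groups' libraries, a panel of 15 stress genes, and up to 4 members of each list with the smallest p. For the bat, at most 2 identifiers per direction are given. Each pipeline was tested on simulated counts drawn from the real libraries' means and sizes. Of genes changed 2-fold and 4-fold, edgeR called 0 and 0% in bat blood (15617 genes), 38 and 84% in bat lung (18927), 41 and 94% in bat muscle (15599), 43 and 93% in mouse blood (15433), 94 and 97% in mouse lung (19144) and 40 and 92% in mouse muscle (17293). Unchanged genes made up 9 of 131 calls in bat lung, 11 of 146 in bat muscle, 24 of 160 in mouse blood, 20 of 211 in mouse lung and 8 of 140 in mouse muscle. These shares, each from a single simulated set, are all above 0.05. For the species difference, 8-fold changes were recovered at 31% in blood (57 genes), 88.5% in lung (76) and 83% in muscle (45).

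Alternatives chosen at the start were DESeq2's size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a log2 change of at least 1, fits of the compared conditions alone, a term for the replicate number, leaving out genes that take over 5% of counts, an estimated correlation for the lists, a mean of at least 5 CPM for the species difference, and each library left out in turn. Correlations between libraries of the same replicate number, over genes and after removal of group means, were not all above 0.1 in a tissue, so the numbers were not taken to pair animals. The exceptions are bat muscle at heat against control, where the 3 same-number correlations were 0.202, 0.183 and 0.168, and bat blood at recovery against control, where they were 0.256, 0.388 and 0.242. These pairings come from the correlations and not from the labels, and the fit with a term for the number is given beside the main one where it moved the count. Runs without the mouse muscle or mouse blood libraries richest in markers of other cells, the test of muscle against lung, and an exchange of bat control and recovery labels in the species difference were added after the data had been seen. Splits of the libraries into other groups numbered 10 for 3 against 3 libraries and 100 drawn with seed 1 for the species difference. Genome coordinates were not used.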

Results

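Gene expression was measured in blood, lung and muscle of 2 mammals, the cave nectar bat and the mouse, before heat shock, right after 1 h of it, and after 4 h of recovery. Each group held 3 libraries, except the mouse blood groups with 2. Total counts ran from 9.29 M (bat lung control 3) to 33.3 M in the bat and from 17.1 to 54.5 M in the mouse. Few genes took a large share of counts in some tissues: the beta-globin gene Hbb-bs held 17.3 to 25.2% of counts in mouse blood, and Ttn, the gene for the muscle protein titin, held 14.9 to 19.7% in mouse muscle. Xist, which is transcribed from the inactive X chromosome of females, reached at least 399 CPM of total counts, without TMM scaling, in mouse libraries numbered 3 (795 in blood control 3) and at most 1.2 in all other mouse libraries. The labels give no sex. Mouse blood heat and recovery held no library with high Xist.

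To determine which genes differed by the end of the heat shock, heat libraries were compared with control libraries. Control animals were sampled at baseline, and no group without heat shock was sampled at the later times. Changes at heat and at recovery thus cannot be told apart from effects of handling or elapsed time. In mouse lung the inducible HSP70 genes Hspa1a and Hspa1b, whose products hold and refold damaged proteins, led the response. Hspa1a rose from 16.4 ± 10.4 CPM in control (SD, n = 3) to 2699 ± 3220 CPM at heat (SD, n = 3), and Hspa1b from 20.1 ± 11.2 to 3229 ± 3810 CPM. These genes are near-identical copies, so the split of reads between them is uncertain. Hsph1, an HSP110 nucleotide exchange factor, rose from 61.4 ± 8.57 to 1318 ± 1260 CPM, the co-chaperone Dnaja1 from 92.8 ± 17.1 to 676 ± 442 CPM, and the cytosolic chaperone Hsp90aa1 from 334 ± 76.2 to 1597 ± 946 CPM. The constitutive HSP70 gene Hspa8 rose from 760 ± 125 to 2393 ± 876 CPM.

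By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 change was 7.37 for Hspa1a (SE 1.43, adjusted p = 0.0418), 7.34 for Hspa1b (SE 1.39, adjusted p = 0.0386) and 4.43 for Hsph1 (SE 0.85, adjusted p = 0.0388). It was 2.26 for Hsp90aa1 (adjusted p = 0.0353) and 1.66 for Hspa8 (adjusted p = 0.0123) in the same edgeR test with Benjamini-Hochberg adjustment. Of the 30 tested heat shock proteins and co-chaperones, 22 rose and none fell (30 rose adjusted over the list alone), with a median log2 change of 1.92. Among them, Chordc1 rose by 1.90, Cacybp by 1.95, Hspa4l by 1.49 and St13 by 0.97 on the log2 scale. The list stood above other genes (camera adjusted p = 1.5e-51, and adjusted p = 0.2 with an estimated correlation) and moved up on balance (fry adjusted p = 0.046). In muscle at heat fry gave an adjusted p of 0.046 too. The list did not pass fry in blood at heat (fry adjusted p = 0.087) or at recovery in muscle (0.065), blood (0.49) or lung (0.81). Many of the other lists called by camera below had a fry adjusted p above 0.05. Dnajb1 (log2 4.02, adjusted p = 0.0528), Hspb1 (3.27, 0.0545), Hspe1 (2.65, 0.063), Hspd1 (2.53, 0.0721) and Bag3 (2.22, 0.0761) did not pass edgeR's test after Benjamini-Hochberg adjustment. Without heat 2 all 5 were called (4.50, 3.66, 3.04, 2.95 and 2.61). Without heat 3 Hspe1 was called at 1.70, and Hspd1 stood at 1.61 and Bag3 at 1.36. Heat library 3 held the highest Hspa1a level (6334 CPM, against 1548 and 215 in heat 1 and 2). Without heat 3 the log2 change was 5.77 for Hspa1a, 5.77 for Hspa1b, 3.32 for Hsph1, 2.25 for Dnaja1 and 2.87 for the small nucleolar RNA Snord14e (4.46 with it), and without control 2 that of Hspa1a was 8.02 and no longer called.

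**Figure D1:**
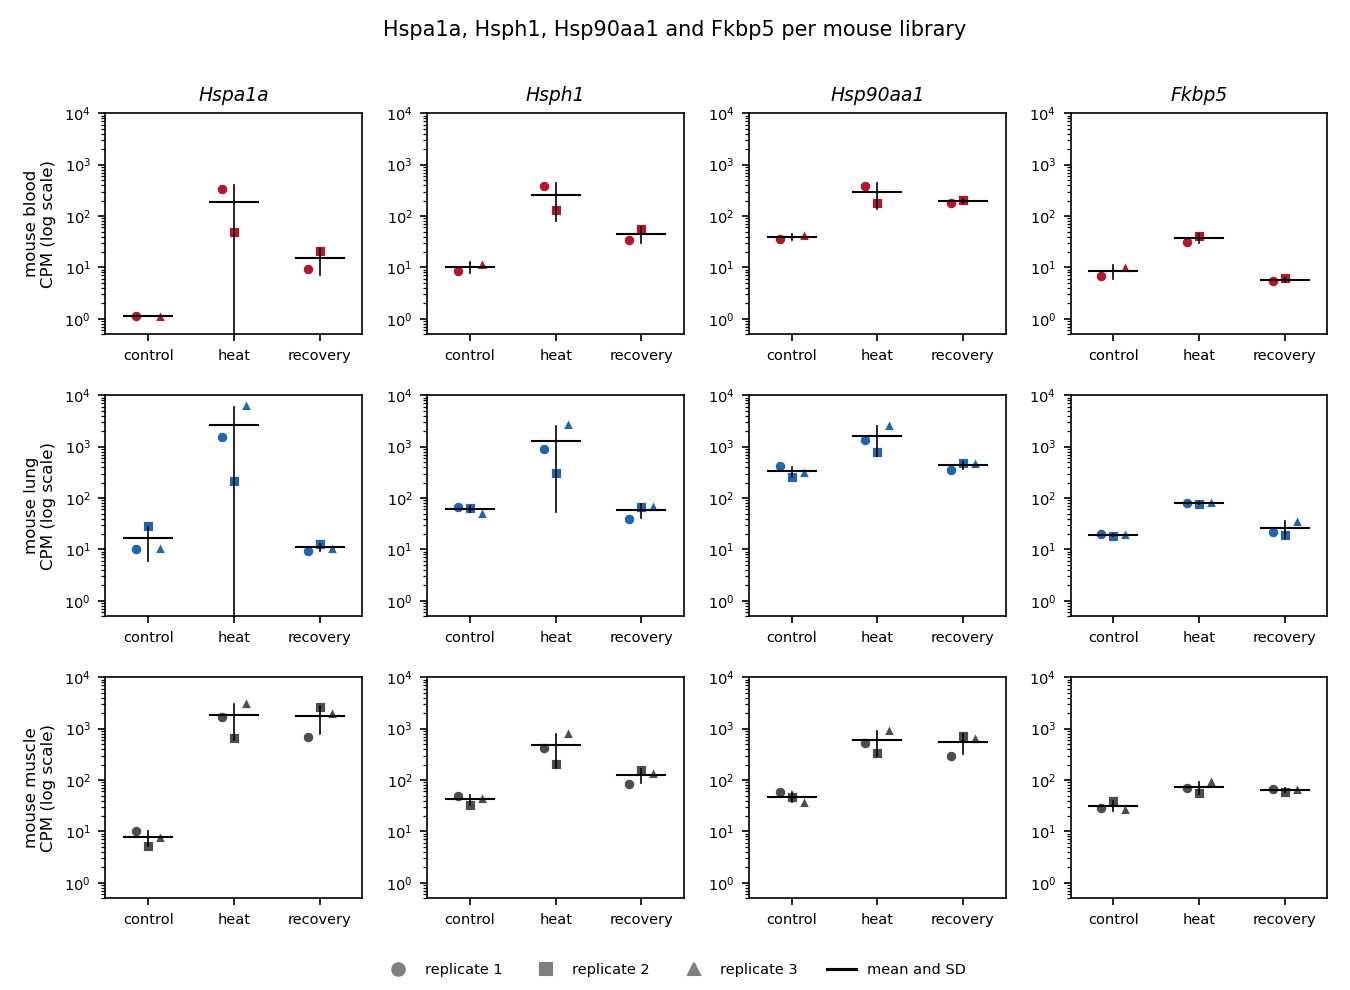
CPM on a log axis of Hspa1a, Hsph1, Hsp90aa1 and Fkbp5 (columns) in mouse blood, lung and muscle (from top to bottom) by condition; symbols are libraries by replicate number, horizontal lines are means and vertical lines span 1 SD to each side, running off the axis where the mean minus the SD is near or below 0. Hspa1a stood near 1764 CPM on average in muscle at recovery and near 11.1 CPM in lung.

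Several glucocorticoid-responsive genes also rose in mouse lung at heat. Fkbp5, a co-chaperone of steroid receptors, rose from 19.1 ± 0.976 to 79.6 ± 4.42 CPM (SD, n = 3 each), and Ddit4, an inhibitor of mTORC1 signalling, from 13.0 ± 2.44 to 55.4 ± 9.28 CPM. Their log2 changes were 2.06 (SE 0.20, adjusted p = 0.00123) and 2.09 (SE 0.16, adjusted p = 0.000307) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 15 members 7 rose (10 adjusted over the list alone), Tsc22d3 by 1.59 and Sult1a1 by 0.74 on the log2 scale, with a median of 1.11 (camera adjusted p = 7e-17, and adjusted p = 0.19 with an estimated correlation). Among genes of endoplasmic reticulum stress, 6 of 26 rose (14 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 1.1e-10, and adjusted p = 0.12 with an estimated correlation). They include Hspa5, the HSP70 of that compartment, at 359 ± 21.8 in control and 530 ± 40.1 CPM at heat (log2 0.56), Creld2 (0.68), Manf (0.52) and Edem1 (0.46). Of mitochondrial chaperones and chaperonin, 8 of 21 rose (9 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 8.8e-06, and adjusted p = 0.44 with an estimated correlation). The chaperonin subunits Cct7 (log2 1.14), Cct4 (0.70), Cct6a (0.60) and Cct5 (0.54) were among them.

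Signalling and damage genes moved in both directions in mouse lung at heat. Of 29 immediate early genes, 3 rose, Dusp1 (a MAP kinase phosphatase, log2 1.23), Ccn2 (1.19) and Klf6 (0.74), and Ier3 fell (-0.56). Adjusted over the list alone, 6 were up and 1 down. The list median was 0.65 (camera adjusted p = 4.9e-06, and adjusted p = 0.5 with an estimated correlation), while Fos (log2 1.20) and Atf3 (2.94) were not called by edgeR (Benjamini-Hochberg adjusted p = 0.158 and 0.113). Without heat 2 both were called (1.59 and 3.45), and without heat 3 Atf3 stood at 1.71. Of 17 p53 targets 4 rose and 1 fell (6 and 1 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at a log2 change of 1.70, Pmaip1 at 1.15, Fas at 0.68 and Plk2 down at -1.33. The median of these targets was 0.22 (camera adjusted p = 0.036, and adjusted p = 0.35 with an estimated correlation). Of 18 inflammatory genes, the decoy receptor Il1r2 (log2 2.23) and the NF-kB inhibitor Nfkbia (0.88) rose and the cytokine Lif fell (-1.56). Of these, 4 were up and 1 down adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.016, and adjusted p = 0.5 with an estimated correlation). Of 20 hypoxia and glycolysis genes, the collagen prolyl hydroxylases P4ha1 (1.96) and P4ha2 (1.27) and the demethylase Kdm3a (0.34) rose and Pdk1 fell (-0.60). Adjusted over the list alone, 4 were up and 2 down, with a median of 0.13 (camera adjusted p = 0.036, and adjusted p = 0.44 with an estimated correlation). Haem oxygenase Hmox1, at 19.4 ± 0.402 in control and 34.0 ± 9.61 CPM at heat (SD, n = 3 each), was the 1 of 20 oxidative stress genes that rose (1 adjusted over the list alone, list median 0.05, camera adjusted p = 0.13).

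Lymphocyte genes were lower in mouse lung at heat. Of 10 B cell markers 6 fell (9 adjusted over the list alone), including Fcrla (log2 -1.17), the IgE receptor Fcer2a (-1.01), Ms4a1, which encodes CD20 (-0.93), and Cd79b of the B cell receptor (-0.90). Their median was -0.89 (camera adjusted p = 2.5e-09, and adjusted p = 0.37 with an estimated correlation), and their summed level was 225, 238 and 213 CPM in the control libraries and 129, 121 and 131 CPM in the heat libraries. Of 18 T and NK cell markers 3 fell (6 adjusted over the list alone), Gzma (-0.96), Cd8a (-0.95) and Cd3e (-0.82), with a median of -0.51 (camera adjusted p = 6.5e-05, and adjusted p = 0.44 with an estimated correlation). The genes that fell most were the linker histone H1f4 (-1.76), the IgD heavy chain Ighd (-1.66), Cd180 of B cells (-1.61), Lif and Cirbp, which encodes a cold-inducible RNA-binding protein. Cirbp fell from 35.7 ± 4.03 to 12.1 ± 1.43 CPM (SD, n = 3 each; log2 -1.56, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.000805). Of 31 interferon-stimulated genes 4 fell (4 adjusted over the list alone), Mx1 (-1.10), Psmb9 (-0.77), Tap1 (-0.75) and Xaf1 (-0.66), with a median of -0.27 (camera adjusted p = 0.0021, and adjusted p = 0.63 with an estimated correlation). None of 13 neutrophil markers passed (0 adjusted over the list alone, median 0.71, camera adjusted p = 0.018, and adjusted p = 0.6 with an estimated correlation).

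The remaining lists in mouse lung at heat did not stand apart from other genes by camera. Their medians were -0.02 for oxidative phosphorylation (camera adjusted p = 0.58), 0.07 for proteasome subunits (0.13), 0.07 for cytosolic ribosomal proteins (0.075), -0.07 for the circadian clock (0.2, with a mean of 0.03), -0.11 for monocytes and macrophages (0.5) and -0.29 for erythroid cells (0.099). Platelet markers had a median of -0.04 (camera adjusted p = 0.99, with a mean of 0.02), lung epithelium 0.09 (0.21), endothelium -0.07 (0.34), fibroblasts and matrix 0.01 (0.77), adipocytes 0.17 (0.63) and slow muscle fibres 0.20 (0.3). Fast muscle fibre markers had under 5 tested members. Ciart of the clock (log2 1.13) and the proteasome subunit Psmd11 (0.32) rose, and the endothelial receptor Kdr fell (-0.37).

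In all, 610 genes rose and 528 fell among 19438 tested in mouse lung at heat (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). In 1137 of these 1138 the heat and control libraries did not overlap, as in 26.9% of all genes tested, where chance gives 10%. The count depended on single libraries: it was 203 without control 1, 531 without control 2, 133 without control 3, 319 without heat 1, 2175 without heat 2, 733 without recovery 1 and 604 without recovery 2, and DESeq2 gave 2156. Of 59 named genes that were called, 39 lost the call without control 1, 24 without control 2, 39 without control 3 and 33 without heat 1. Calls of 3 were lost without heat 2, 10 without heat 3, and 15, 17 and 16 without recovery 1, 2 and 3, and none turned direction in these runs. Called in each of these runs were 17 of them: Cacybp, Chordc1, Hspa4l, St13, Cct4, Creld2, Fkbp5, Ddit4, Cirbp, Ciart, Ier3, Nfkbia, Pdk1, Plk2, Pmaip1, Psmb9 and Tap1.

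The recovery libraries show where expression stood 4 h after the heat shock. In mouse lung Hspa1a and Hsph1 were then below their heat levels, with Hspa1a at 11.1 ± 1.81 CPM and Hsph1 at 58.7 ± 17 CPM (SD, n = 3). Their log2 changes from heat to recovery were -7.93 (adjusted p = 0.0246) and -4.49 (adjusted p = 0.0252) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Between heat and recovery 25 of 30 heat shock proteins and co-chaperones fell (28 adjusted over the list alone, median -1.98, camera adjusted p = 4.5e-46, and adjusted p = 0.37 with an estimated correlation). Hspa8 fell by 2.78, Hsp90aa1 by 1.87, Fkbp5 by 1.61 and Hspa5 by 1.04 on the log2 scale over that interval. Hspb1 stood at 354 ± 104 CPM, against 93.3 ± 33.4 in control and 898 ± 797 at heat (SD, n = 3 each), and was called by edgeR neither against heat (log2 -1.34, Benjamini-Hochberg adjusted p = 0.253) nor against control (1.93, 0.639). Against control none of the 30 passed (0 up and 1 down adjusted over the list alone, median -0.09, camera adjusted p = 0.11). Without heat 2 or recovery 2 the list was called lower than control, with medians of -0.09 and -0.14 (camera adjusted p = 0.0067 and 0.049). Hspa1a had a log2 change of -0.55 against control (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.97), which was 0.09 without control 2.

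Against control, 4 genes rose and 2 fell among 19438 in mouse lung at recovery. Lox, a collagen and elastin cross-linking enzyme, rose from 101 ± 9.42 to 184 ± 26.4 CPM, Galnt15 from 47.6 ± 5.58 to 94.0 ± 18.3 CPM and Akr1c14 from 43.5 ± 3.47 to 83.9 ± 14.3 CPM (SD, n = 3 each). The vascular peptide gene Apln fell from 46.6 ± 9.68 to 22.8 ± 2.52 CPM and the cadherin gene Fat3 from 72.1 ± 8.3 to 42.1 ± 2.99 CPM. Log2 changes were 0.98 (Galnt15), 0.95 (Akr1c14), 0.86 (Lox), -1.03 (Apln) and -0.77 (Fat3), each with an adjusted p of 0.0436 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These calls rest on few libraries: all 5 were lost without control 1, 2 or 3, heat 1 or 2, or recovery 2 or 3, and 4 without recovery 1. The count was 1 without control 1 or control 3, 0 without control 2, heat 1, heat 2, recovery 2 or recovery 3, 2 without recovery 1 and 62 without heat 3, while DESeq2 gave 117.

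Markers of T and NK cells were lower in mouse lung at recovery than in control (0 of 18 called, 6 down adjusted over the list alone, median -0.42, camera adjusted p = 3.9e-11, and adjusted p = 0.2 with an estimated correlation). So were B cell markers (0 of 10 called, 0 adjusted over the list alone, median -0.34, camera adjusted p = 8.9e-07, and adjusted p = 0.44 with an estimated correlation), with sums of 240, 164 and 115 CPM in the recovery libraries. Endoplasmic reticulum stress genes had a median of -0.14 (0 of 26 called, 4 down adjusted over the list alone, camera adjusted p = 1.3e-05, and adjusted p = 0.19 with an estimated correlation). Adipocyte markers had a median of 0.95 (0 of 8 called, 0 adjusted over the list alone, camera adjusted p = 1.4e-08, and adjusted p = 0.33 with an estimated correlation). Their sums were 88.1, 42.4 and 80 CPM in control and 104, 139 and 123 CPM at recovery. Lists of other blood cells were lower too, with 0 members called and 0 adjusted over the list alone: neutrophil markers (median -0.44, camera adjusted p = 0.016, and adjusted p = 0.6 with an estimated correlation) and erythroid markers (-0.32, camera adjusted p = 0.036, and adjusted p = 0.68 with an estimated correlation). Neutrophil sums were 87.1, 104 and 113 CPM in control and 52.7, 127 and 83.9 CPM at recovery, and erythroid sums 7210, 8210 and 6950 CPM in control and 5630, 7550 and 2880 CPM at recovery. Small upward shifts with 0 members called and 0 adjusted over the list alone were seen for oxidative phosphorylation (0.06, camera adjusted p = 0.038, and adjusted p = 0.63 with an estimated correlation), the proteasome (0.06, camera adjusted p = 0.022, and adjusted p = 0.67 with an estimated correlation) and slow fibre markers (0.27, camera adjusted p = 0.034, and adjusted p = 0.48 with an estimated correlation).

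Skeletal muscle of the mouse carried an HSP70 response at heat as well. Hspa1b rose from 6.14 ± 1.79 to 1979 ± 1280 CPM and Hspa1a from 7.78 ± 2.46 to 1840 ± 1240 CPM (SD, n = 3 each; the split between the copies is uncertain). Hsp90aa1 rose from 47.7 ± 11 to 596 ± 300 CPM and Hsph1 from 41.9 ± 8.54 to 485 ± 316 CPM. The small heat shock protein gene Hspb1 rose from 81.4 ± 9.9 to 512 ± 181 CPM, and Nle1 from 6.85 ± 0.765 to 166 ± 65.8 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 changes were 8.33 (SE 0.81, adjusted p = 0.0178) for Hspa1b, 7.89 (adjusted p = 0.0197) for Hspa1a, 4.60 (0.027) for Nle1, 3.64 (0.027) for Hsp90aa1, 3.53 (0.039) for Hsph1 and 2.65 (0.027) for Hspb1. The HSP90 co-chaperone Ahsa2 rose as well (2.49, 0.0178). In all 9 of 30 heat shock proteins and co-chaperones rose (30 adjusted over the list alone, median 1.70, camera adjusted p = 1.7e-49, and adjusted p = 0.2 with an estimated correlation). Dnajb1 (log2 5.65), Atf3 (3.51), Fkbp5 (1.21) and Hspa8 (1.19) were not called by edgeR (Benjamini-Hochberg adjusted p = 0.0678, 0.0693, 0.0528 and 0.0674). All 4 were called without recovery 1 (5.65, 3.50, 1.21 and 1.19), Dnajb1 also without recovery 2 (5.68), Fkbp5 without heat 2 (1.36) and Hspa8 without control 3 (1.39).

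Among the other stress groups in mouse muscle at heat, the metal-binding gene Mt1 (log2 2.85) and Cebpd (1.46) were the 2 of 15 glucocorticoid-responsive genes that rose (8 up and 1 down adjusted over the list alone, median 0.95, camera adjusted p = 5.9e-07, and adjusted p = 0.19 with an estimated correlation). P4ha1 (2.19) and P4ha2 (1.62) rose among 20 hypoxia and glycolysis genes (2 adjusted over the list alone, median 0.38, camera adjusted p = 0.0025, and adjusted p = 0.35 with an estimated correlation). Nfil3 (2.16) rose among 18 clock genes (3 adjusted over the list alone, median 0.18, camera adjusted p = 0.011, and adjusted p = 0.48 with an estimated correlation). Cct3 (0.72) rose among 21 mitochondrial chaperones and chaperonin (11 adjusted over the list alone, median 0.40, camera adjusted p = 1e-07, and adjusted p = 0.48 with an estimated correlation). No immediate early gene of 28 passed (7 adjusted over the list alone, median 0.54, camera adjusted p = 7.1e-05, and adjusted p = 0.48 with an estimated correlation). Genes of oxidative phosphorylation shifted up as a list with 0 members called (median 0.41, camera adjusted p = 4.2e-10, and adjusted p = 0.49 with an estimated correlation). The proteasome (0.37, camera adjusted p = 1e-07, and adjusted p = 0.53 with an estimated correlation) and fast fibre genes (0.52, camera adjusted p = 0.0065, and adjusted p = 0.5 with an estimated correlation) did so too, with 0 members called in each. Fast fibre sums were 65400 and 61200 CPM in control 1 and 2, which were rich in B cell and adipocyte markers, 97600 CPM in control 3, and 115000, 108000 and 1e+05 CPM at heat. Slow fibre markers (median 1.39, camera adjusted p = 0.52) and endoplasmic reticulum stress genes (-0.01, camera adjusted p = 0.81) did not stand apart.

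Immune, fat and vessel genes were lower in mouse muscle at heat. Sox18, an endothelial transcription factor, fell from 9.66 ± 1.26 to 1.97 ± 0.449 CPM (SD, n = 3 each; log2 -2.29, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0178), and Ddx60 (-2.24), Engase (-1.54), Xaf1 (-1.47) and Tril (-1.30) fell. Of 32 interferon-stimulated genes 1 fell (20 adjusted over the list alone, median -1.09, camera adjusted p = 2.7e-10, and adjusted p = 0.48 with an estimated correlation). Markers of T and NK cells (median -4.00, camera adjusted p = 6.2e-05, and adjusted p = 0.53 with an estimated correlation) and B cells (-3.62, camera adjusted p = 0.0058, and adjusted p = 0.6 with an estimated correlation) had 0 members called. So had markers of adipocytes (-2.47, camera adjusted p = 0.00027, and adjusted p = 0.48 with an estimated correlation) and macrophages (-1.46, camera adjusted p = 3.6e-05, and adjusted p = 0.48 with an estimated correlation). Nor was any member called among fibroblast and matrix markers (-0.65, camera adjusted p = 0.00016, and adjusted p = 0.48 with an estimated correlation), endothelial markers (-0.39, camera adjusted p = 0.03, and adjusted p = 0.63 with an estimated correlation) or inflammatory genes (-0.84, camera adjusted p = 0.022, and adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 8 macrophage, 5 fibroblast and 4 endothelial markers fell, and no B cell, T cell, adipocyte or inflammatory gene passed. These markers varied between libraries of 1 condition. The B cell sum was 191, 143 and 51.7 CPM in control, 2.14, 16.4 and 17.9 CPM at heat, and 335, 2.55 and 0.984 CPM at recovery. The adipocyte sum was 1720, 2260 and 922 CPM in control, 464, 613 and 858 CPM at heat, and 1860, 711 and 1020 CPM at recovery.

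**Figure D2:**
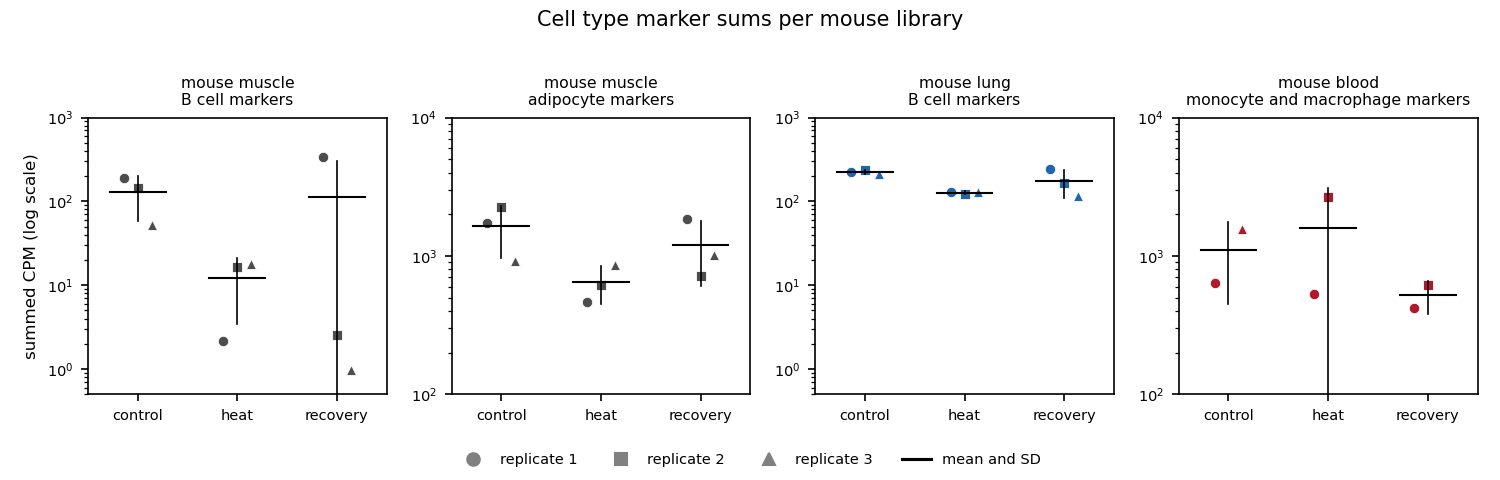
Summed CPM (log axis) of B cell and adipocyte markers in mouse muscle, B cell markers in mouse lung, and monocyte and macrophage markers in mouse blood, by condition; symbols are libraries, horizontal lines are means and vertical lines span 1 SD to each side, running off the axis where the mean minus the SD is near or below 0. In muscle, recovery 1 reached 335 CPM of B cell markers and the other recovery libraries at most 2.55 CPM.

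In total 52 genes rose and 24 fell among 17746 in mouse muscle at heat (edgeR quasi-likelihood, Benjamini-Hochberg), all 76 without overlap between the groups' libraries, against 37.7% of all genes and 10% by chance. The count was 0 without control 1, control 2 or heat 1, 377 without control 3, 129 without heat 2, 11 without heat 3, 2742 without recovery 1 and 41 without recovery 3, and DESeq2 gave 2362. Of the 18 named genes called, all 18 lost the call without control 1, control 2 or heat 1, 4 without heat 2, 13 without heat 3, 5 without recovery 2 and 8 without recovery 3. Without heat 3 the log2 change was 7.27 for Hspa1a and 2.91 for Hsph1. A run added after the data were seen left out the 3 libraries richest in lymphoid markers (control 1, control 2 and recovery 1). Control then held 1 library, so only the size of the change is given. Hspa1a had a log2 change of 7.86 in that run, against 7.89 in the main fit.

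At recovery the HSP70 genes were still high in mouse muscle. Hspa1a stood at 1764 ± 965 and Hspb1 at 712 ± 270 CPM, and Tnfrsf12a, the receptor of the cytokine TWEAK, rose from 5.82 ± 1.45 to 58.9 ± 7.29 CPM (SD, n = 3 each). The metallothionein gene Mt2 rose from 1.54 ± 0.577 to 34.4 ± 17.4 CPM, and Xirp1, which encodes an actin-binding protein of striated muscle, from 130 ± 33.1 to 1349 ± 525 CPM. Log2 changes against control were 8.11 for Hspa1b (SE 0.81, adjusted p = 0.0154), 7.83 for Hspa1a (0.0154) and 4.48 for Mt2 (0.0154) by edgeR with Benjamini-Hochberg adjustment. They were 3.38 for Xirp1 (0.0154), 3.34 for Tnfrsf12a (SE 0.23, adjusted p = 0.00274), 3.21 for Mt1 (0.0154) and 3.13 for Hspb1 (0.0182) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hsp90aa1 (551 ± 229 CPM, log2 3.53) and the stress transcription factor Atf3 (89.3 ± 60.4 CPM, against 2.77 ± 1.17 in control) were not called by edgeR (Benjamini-Hochberg adjusted p = 0.0574 and 0.112). Hsp90aa1 was called without heat 2 (3.53), heat 3 (3.53) or recovery 1 (3.84). Of 30 heat shock proteins and co-chaperones 3 rose (27 adjusted over the list alone, median 1.38, camera adjusted p = 2.5e-95, and adjusted p = 0.12 with an estimated correlation). Between heat and recovery 1 of them fell (2 adjusted over the list alone, median -0.32, camera adjusted p = 0.00013, and adjusted p = 0.68 with an estimated correlation).

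Of the other groups in mouse muscle at recovery, 2 of 15 glucocorticoid-responsive genes rose (3 adjusted over the list alone, median 0.10, camera adjusted p = 3.6e-06, and adjusted p = 0.2 with an estimated correlation). No oxidative stress gene was called (4 up adjusted over the list alone, median 0.24, camera adjusted p = 1.5e-06, and adjusted p = 0.12 with an estimated correlation). Nor was a ribosomal protein gene called (0 adjusted over the list alone, median 0.16, camera adjusted p = 1.3e-07, and adjusted p = 0.48 with an estimated correlation). Other lists that stood higher with 0 members called were clock genes (median 0.23, camera adjusted p = 6.5e-05, and adjusted p = 0.35 with an estimated correlation), immediate early genes (0.20, camera adjusted p = 0.00052, and adjusted p = 0.49 with an estimated correlation), mitochondrial chaperones and chaperonin (0.17, camera adjusted p = 0.00012, and adjusted p = 0.54 with an estimated correlation) and oxidative phosphorylation (0.17, camera adjusted p = 1.6e-05, and adjusted p = 0.6 with an estimated correlation). So did proteasome subunits (0.16, camera adjusted p = 0.00016, and adjusted p = 0.63 with an estimated correlation), hypoxia and glycolysis genes (0.20, camera adjusted p = 0.0042, and adjusted p = 0.39 with an estimated correlation), p53 targets (0.26, camera adjusted p = 0.035, and adjusted p = 0.35 with an estimated correlation) and fast fibre markers (0.28, camera adjusted p = 0.02, and adjusted p = 0.54 with an estimated correlation). Lower, with 0 called, were erythroid markers (-0.48, camera adjusted p = 0.001, and adjusted p = 0.35 with an estimated correlation), B cell markers (-0.15, camera adjusted p = 0.00048, and adjusted p = 0.53 with an estimated correlation) and T and NK cell markers (-0.33, camera adjusted p = 0.002, and adjusted p = 0.6 with an estimated correlation). Adjusted over the list alone, 3 immediate early and 2 clock genes rose and no member of the other 9 lists passed. The B cell sum was 191, 143 and 51.7 CPM in control and 335, 2.55 and 0.984 CPM at recovery. The T and NK cell sum was 102, 60 and 47.7 CPM in control and 138, 31.1 and 26.4 CPM at recovery. In both sums recovery 1 stood above every control library. Slow fibre markers were higher (0 of 8 called, 0 adjusted over the list alone, median 2.14, camera adjusted p = 0.00092, and adjusted p = 0.5 with an estimated correlation). Their sums were 276, 406 and 165 CPM in control, 94.8, 211 and 1400 CPM at heat, and 1610, 1210 and 194 CPM at recovery. In total 12 genes rose and 0 fell among 17746 (edgeR quasi-likelihood, Benjamini-Hochberg; 879 at an unadjusted p under 0.05, DESeq2 101), all 12 without overlap, against 9.52% of all genes and 10% by chance. The count was 1 without control 1 or control 2, 4 without control 3, 7 without recovery 2 and 45 without recovery 1. Of the 7 named genes called, 6 lost the call without control 1, 2 or 3, 1 without heat 1 or recovery 3, and 3 without recovery 2, and Tnfrsf12a was called in all 9 runs. A run added after the data were seen left out control 1, control 2 and recovery 1. Control then held 1 library, so only the size of the change is given. Hspa1a had a log2 change of 8.18 at recovery in that run, against 7.83 in the main fit.

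Whether muscle and lung of the mouse differed in these responses was tested on the 15 panel genes, in an edgeR fit added after the data were seen (quasi-likelihood, Benjamini-Hochberg over 30 tests). The fit treats all libraries as independent, and whether lung and muscle came from the same animals is not given in the sources used here. At recovery the change was larger in muscle than in lung for Hspa1a (difference 8.40 on the log2 scale, SE 1.41, adjusted p = 0.000142) and Hsp90aa1 (3.15, adjusted p = 0.000515). The same held for Hspa8 (2.11, adjusted p = 0.000142) and Atf3 (5.35, adjusted p = 0.000685), with Hspa1b, Dnajb1, Bag3 and Hspa5 also called. At heat none of the 15 differed by that edgeR test; Fkbp5 came nearest, at -0.83 (Benjamini-Hochberg adjusted p = 0.0529).

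In mouse blood, with 2 libraries per group, no gene was called at heat by edgeR (quasi-likelihood with Benjamini-Hochberg, 2355 of 15869 at an unadjusted p under 0.05), while DESeq2 called 519. Hspa1a stood at 1.13 ± 0.0101 CPM in control and 192 ± 203 CPM at heat, Hsph1 at 10.1 ± 2.42 and 260 ± 180 CPM, and Hsp90aa1 at 39.6 ± 4.61 and 288 ± 149 CPM (SD, n = 2 each). Without heat 2 their log2 changes were 8.22, 5.26 and 3.31, and that of Hsp90aa1 was 2.20 without heat 1. Heat held 1 library in these runs, so only the size of the change is given. Hspa1a was at 335.3 CPM in heat 1 and 48.03 CPM in heat 2. The clock and glucocorticoid gene Per1 had the smallest adjusted p, at 15.0 ± 0.466 and 50.2 ± 3.66 CPM (log2 1.75, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0563). As a list, heat shock proteins and co-chaperones were higher (0 of 27 called, 24 up adjusted over the list alone, median 1.88, camera adjusted p = 7.9e-50, and adjusted p = 0.33 with an estimated correlation). So were immediate early genes (0 of 26 called, 11 adjusted over the list alone, median 0.72, camera adjusted p = 9.4e-12, and adjusted p = 0.44 with an estimated correlation). Inflammatory genes were higher too (0 of 18, 11 adjusted over the list alone, median 0.99, camera adjusted p = 5.4e-11, and adjusted p = 0.33 with an estimated correlation), as were glucocorticoid-responsive genes (0 of 14, 7 adjusted over the list alone, median 1.28, camera adjusted p = 2.7e-10, and adjusted p = 0.35 with an estimated correlation).

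Cell markers of mouse blood also differed at heat. Neutrophil markers were higher (0 of 14 called, 7 adjusted over the list alone, median 0.77, camera adjusted p = 2.6e-08, and adjusted p = 0.47 with an estimated correlation). Their sums were 447 and 502 CPM in control and 980 and 811 CPM at heat. B cell markers were lower (0 of 10 called, 7 down adjusted over the list alone, median -0.54, camera adjusted p = 2.5e-05, and adjusted p = 0.48 with an estimated correlation). Other lists that stood higher with 0 members called were p53 targets (median 0.26, camera adjusted p = 0.00023, and adjusted p = 0.31 with an estimated correlation), endoplasmic reticulum stress genes (0.31, camera adjusted p = 0.001, and adjusted p = 0.48 with an estimated correlation), oxidative stress genes (0.35, camera adjusted p = 0.0013, and adjusted p = 0.48 with an estimated correlation), hypoxia and glycolysis genes (0.31, camera adjusted p = 0.0013, and adjusted p = 0.33 with an estimated correlation) and mitochondrial chaperones and chaperonin (0.15, camera adjusted p = 0.0036, and adjusted p = 0.48 with an estimated correlation). Ribosomal protein genes stood lower with 0 called (-0.12, camera adjusted p = 0.0078, and adjusted p = 0.77 with an estimated correlation). Adjusted over the list alone, 4 p53 targets, 1 gene of endoplasmic reticulum stress, 1 of oxidative stress and 9 chaperones rose, 3 hypoxia genes rose and 1 fell, and no ribosomal protein gene passed. Monocyte and macrophage markers varied between libraries of 1 condition. Their sum was 641 CPM in control 1, 1560 in control 3, 527 in heat 1, 2670 in heat 2, and 421 and 618 at recovery. The count of called genes at heat was 5 without control 1, 43 without heat 1 and 736 without heat 2. Without control 3 and heat 2, a run added after the data were seen, edgeR called 2801 genes at heat and 992 at recovery. Each compared group but recovery then held 1 library, which was assumed to vary like the recovery libraries. In the runs that left out a single library, the group it came from also held 1 library.

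At recovery no gene of mouse blood was called against control by edgeR (quasi-likelihood with Benjamini-Hochberg, 1417 of 15869 at an unadjusted p under 0.05), while DESeq2 called 74. The count was 5 without control 1 and 1 without heat 1 or heat 2. In each of these runs 1 group held 1 library, assumed to vary like the other groups. With all libraries Hspa1a stood at 15.2 ± 8.16 CPM at recovery and Hsp90aa1 at 196 ± 19.7 CPM (SD, n = 2). Between heat and recovery several stress genes fell: Hmox1 by 4.28, Atf3 by 3.17, Dusp1 by 2.93, Hspd1 by 2.77, Fkbp5 by 2.65, Dnajb1 by 2.27, Hspa8 by 2.07 and Fos by 1.84 on the log2 scale. Of 27 heat shock proteins and co-chaperones 14 fell over that interval (22 adjusted over the list alone, median -1.96, camera adjusted p = 1.4e-21, and adjusted p = 0.48 with an estimated correlation). Against control that list had a median of 0.10 (0 called, 1 adjusted over the list alone, camera adjusted p = 4e-04, and adjusted p = 0.64 with an estimated correlation). Erythroid markers were higher than in control (0 of 12 called, 3 adjusted over the list alone, median 0.97, camera adjusted p = 8.4e-11, and adjusted p = 0.48 with an estimated correlation). So were platelet markers (0 of 12, 0 adjusted over the list alone, median 1.07, camera adjusted p = 7.6e-10, and adjusted p = 0.48 with an estimated correlation). Control 3 was low in both erythroid and platelet markers, with an erythroid sum of 401000 CPM against 573000 in control 1 and 772000 and 918000 at recovery, and a platelet sum of 1120 CPM against 2320, 3440 and 3770. Neutrophil markers were lower (0 of 14 called, 0 adjusted over the list alone, median -0.68, camera adjusted p = 1.5e-05, and adjusted p = 0.48 with an estimated correlation), with sums of 243 and 357 CPM at recovery and 447 and 502 CPM in control. Immediate early genes were lower as a list (0 called, 3 adjusted over the list alone, median -0.70, camera adjusted p = 2.9e-09, and adjusted p = 0.48 with an estimated correlation). Inflammatory (-0.77, camera adjusted p = 7.4e-09, and adjusted p = 0.35 with an estimated correlation) and macrophage genes (-2.40, camera adjusted p = 4e-06, and adjusted p = 0.5 with an estimated correlation) were lower as well, with 0 members called and 2 and 1 down adjusted over the list alone. Control 3 stands apart in the macrophage markers, whose sum was 1560 CPM there, 641 CPM in control 1, and 421 and 618 CPM at recovery. Also lower, with 0 members called, were fibroblast and matrix markers (-3.79, camera adjusted p = 0.0013, and adjusted p = 0.5 with an estimated correlation), glucocorticoid-responsive genes (-0.75, camera adjusted p = 0.00021, and adjusted p = 0.48 with an estimated correlation), endoplasmic reticulum stress genes (-0.35, camera adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation) and T and NK cell markers (-0.04, camera adjusted p = 0.036, and adjusted p = 0.68 with an estimated correlation). Higher, with 0 members called, were endothelial markers (0.86, camera adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation) and B cell markers (0.22, camera adjusted p = 0.017, and adjusted p = 0.6 with an estimated correlation). Adjusted over the list alone, 1 glucocorticoid-responsive gene and no member of the other 5 lists passed. Fibroblast sums were 14.4 CPM in control 3 and 1.38 CPM in control 1, and endothelial sums 259 and 479 CPM.

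The bat libraries were compared in the same way, with genes given by identifier. In bat lung at heat no gene was called by edgeR (quasi-likelihood with Benjamini-Hochberg, 1662 of 19149 at an unadjusted p under 0.05), while DESeq2 called 18. At recovery 3 rose and 6 fell, all 9 of them rows with human Ensembl identifiers. ENSG00000204389 fell from 3662 ± 531 CPM in control to 41.3 ± 10.9 CPM, and ENSG00000204388 from 2641 ± 97.5 to 29.9 ± 1.59 CPM (SD, n = 3 each). Their heat levels were 3473 ± 2890 and 2707 ± 2390 CPM, with ENSG00000204389 at 813.4, 6551 and 3053 CPM in heat 1, 2 and 3. ENSG00000160145 rose from 76.3 ± 6.54 to 252 ± 46.4 CPM and ENSG00000151117 from 15.7 ± 0.146 to 35.7 ± 2.18 CPM. The log2 changes were -6.47 (SE 0.71), -6.47 (SE 0.73), 1.72 (SE 0.20) and 1.19 (SE 0.14), each with an adjusted p of 0.0225 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 950 genes. In all 9 the libraries did not overlap, as in 20.6% of all genes and 10% by chance.

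The calls in bat lung at recovery rest on few libraries. All 4 identifiers lost the call without control 1, control 2, recovery 1, recovery 2 or recovery 3, 3 without heat 3 and 1 without heat 2. The count was 0 without control 1, control 2 or any 1 recovery library, 2 without heat 3, 22 without heat 1 and 62 without control 3. The log2 change of ENSG00000204389 lay between -6.59 and -6.26 in these runs.

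**Figure D3:**
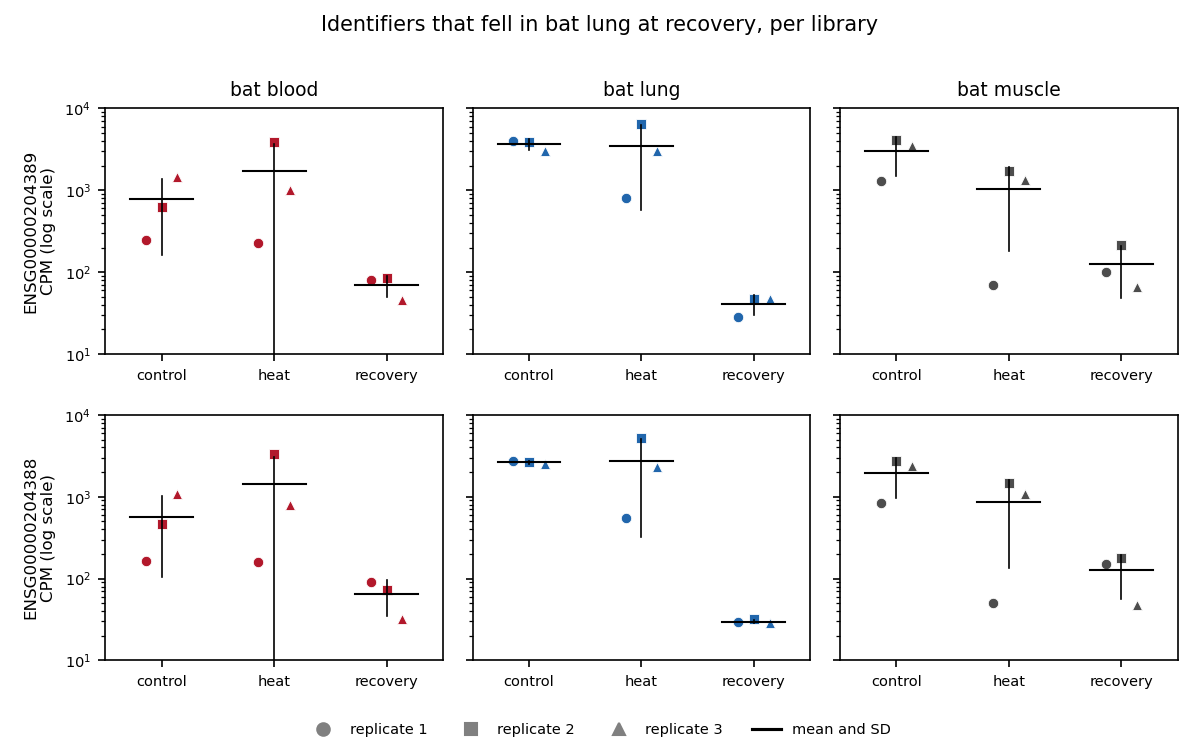
CPM on a log axis of ENSG00000204389 (top) and ENSG00000204388 (bottom) in bat blood, lung and muscle by condition; symbols are libraries, horizontal lines are means and vertical lines span 1 SD to each side, running off the axis where the mean minus the SD is near or below 0. In lung ENSG00000204389 averaged 3662 CPM in control and 41.3 CPM at recovery.

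In bat muscle 6 genes fell and 0 rose among 15950 at heat (edgeR quasi-likelihood, Benjamini-Hochberg; 2840 at an unadjusted p under 0.05, DESeq2 778). ENSG00000173334 fell from 44.5 ± 6.42 to 16.8 ± 1.34 CPM and ENSG00000105355 from 115 ± 21.6 to 47.5 ± 1.73 CPM (SD, n = 3 each). Their log2 changes were -1.41 (SE 0.15, adjusted p = 0.023) and -1.27 (adjusted p = 0.0493) by edgeR with Benjamini-Hochberg adjustment. In all 6 the libraries did not overlap, as in 25.4% of all genes and 10% by chance. With a block for the replicate number, which the correlations of control and heat libraries pair in this comparison, the count was 63 and both identifiers were called. The labels give no such pairing. The block also covers the recovery libraries, whose same-number correlations were 0.073, 0.174 and 0.033 with control and 0.065, 0.045 and 0.029 with heat. Both identifiers lost the call without control 1, control 3, heat 1, heat 2 or heat 3, and ENSG00000105355 also without control 2 or recovery 1. The count was 0 without control 1, control 3, heat 1, heat 2 or heat 3, 2 without control 2, 31 without recovery 2 and 104 without recovery 3.

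At recovery bat muscle showed 187 genes that rose and 239 that fell (edgeR quasi-likelihood, Benjamini-Hochberg; DESeq2 1523), all 426 without overlap between the groups' libraries, as in 26.4% of all genes and 10% by chance. ENSG00000073282 rose from 2.14 ± 1.08 to 14.8 ± 3.40 CPM and ENSG00000005981 from 20.5 ± 7.91 to 107.8 ± 29 CPM. ENSG00000132002 fell from 98.6 ± 35.3 to 5.15 ± 2.24 CPM and ENSG00000178381 from 59.1 ± 50.4 to 4.64 ± 1.53 CPM (SD, n = 3 each). Log2 changes were 2.80 (adjusted p = 0.0163), 2.39 (0.0163), -4.26 (0.0307) and -3.67 (0.045) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Rows with human Ensembl identifiers made up 137 of the genes that rose and 214 of those that fell, and non-coding RNA rows 45 and 24. The count was 93 without control 1, 115 without control 2, 243 without control 3, 165 without heat 2, 206 without heat 3, 17 without recovery 1 and 74 without recovery 2. Of the 4 identifiers, 3 lost the call without control 1, 3 without control 2, 2 without control 3, 2 without heat 2, 1 without heat 3, 4 without recovery 1 and 2 without recovery 2. Without control 2 the log2 change of ENSG00000178381 was -2.74. ENSG00000204389 and ENSG00000204388, which fell in lung, had log2 changes of -4.55 and -3.97 in muscle at recovery and were not called by edgeR (Benjamini-Hochberg adjusted p = 0.0628 and 0.0849).

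In bat blood no gene was called at heat (351 of 16038 at an unadjusted p under 0.05, DESeq2 0) or at recovery (849 at an unadjusted p under 0.05, DESeq2 95) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ENSG00000204389 stood at 778.1 ± 615 CPM in control, 1725 ± 1960 at heat and 70.01 ± 20.8 at recovery (SD, n = 3 each), with a log2 change at recovery of -3.47 (edgeR, Benjamini-Hochberg adjusted p = 0.778). In bat blood counts simulated with 100 genes changed 2-fold and 100 changed 4-fold, edgeR called none of them. Changes of that size in single genes were thus not detected by this edgeR test. Other tests, or more genes changed, were not simulated. The libraries of bat blood varied most, with a coefficient of variation of 0.536, and recovery 2 had the lowest correlation with the rest of its tissue (0.8527).

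Whether the bat's response differed from the mouse's, the question the series was designed for, was tested on rows with a shared symbol. No gene of the 15-gene panel was among those rows, and Ahsa2 was the 1 member of the heat shock list there. Rows with human identifiers carry no gene names in the sources used here. They could not be matched to the panel or the list and may include their members. In lung at heat Ahsa2 stood at 16.95 ± 15.2 CPM in control and 12.13 ± 0.509 CPM at heat in the bat, and at 32.85 ± 7.17 and 203.8 ± 75.7 CPM in the mouse (SD, n = 3 each). Its log2 change was -0.47 in the bat and 2.64 in the mouse, a difference of -3.10 (SE 0.61, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.00494), and -2.06 without bat lung control 3. It was called in all 18 runs that left out 1 library. Cmah (difference 1.04, SE 0.29) and Fbxw17 (1.08, SE 0.32) also differed in lung (edgeR, Benjamini-Hochberg adjusted p = 0.0472 each), 5 genes of 76 in all. In muscle at heat Cox8b, a subunit of cytochrome oxidase, had log2 changes of -0.95 in the bat and 0.35 in the mouse (difference -1.30, SE 0.31, edgeR with Benjamini-Hochberg adjusted p = 0.0272), 1 of 4 called among 45. Ahsa2, named here after its value was seen since its mean of 4.51 CPM in bat muscle is below the minimum set, had 0.64 and 2.49 (difference -1.85, SE 0.50, edgeR with Benjamini-Hochberg adjusted p = 0.029).

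An exchange of the bat control and recovery labels stays open. With them exchanged, a run added after the data were seen, the difference at heat in lung was -1.99 for Ahsa2 and 0.57 for Cmah, neither called by edgeR (Benjamini-Hochberg adjusted p = 0.144 and 0.294), and 1.83 for Fbxw17, which was called. In muscle that of Cox8b was -0.72 and not called by edgeR (Benjamini-Hochberg adjusted p = 0.2), and that of Ahsa2 was -1.90 and called.

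Several of these species differences rest on single libraries. In lung the count was 12 without bat control 1 or bat control 2, 2 without bat control 3 or mouse recovery 3, 3 without bat heat 3 and 8 without bat recovery 3. It was 1 without mouse control 1, 2 or 3, mouse heat 1 or 3, or mouse recovery 1 or 2. Cmah (0.94 to 1.11) and Fbxw17 (0.92 to 1.11) both lost the call without bat control 3, bat heat 2, mouse control 1, 2 or 3, mouse heat 1 or 3, or mouse recovery 1 or 2. Cmah also lost it without bat heat 1, and Fbxw17 without bat control 1 (0.95), bat heat 3 (0.88) or mouse recovery 3. Cox8b in muscle lost the call without bat heat 1 (-1.22), bat heat 3 (-1.37), mouse control 1 (-1.26) or mouse control 2 (-1.30). In muscle the count was 0 without bat heat 1 or 3 or mouse control 1 or 2, 2 without bat control 3 or any 1 mouse heat library, and 7 without mouse recovery 1. The muscle call of Ahsa2 was lost without bat control 3 (difference -1.26), bat heat 1, 2 or 3, mouse control 1 or 2, or mouse heat 1 or 3, where it lay between -1.98 and -1.68 except without bat control 3. No gene differed in blood at heat (3 of 57 at an unadjusted p under 0.05, DESeq2 0) or at recovery (0; DESeq2 0), in lung at recovery (17 of 76; DESeq2 4) or in muscle at recovery (2 of 45; DESeq2 0) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ahsa2 in blood at heat had a difference of -2.44 (edgeR, Benjamini-Hochberg adjusted p = 0.382).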

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

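The tests of the mouse muscle and lung difference and those of the patterns below were chosen after the results were seen, except that the list of serous cavity macrophage markers was written before their values were seen and the splits of the libraries were set at the start. Groups of 3 or fewer libraries were too small to test single libraries as far from the others.

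In the mouse the change at recovery differed between muscle and lung by edgeR's quasi-likelihood test (Benjamini-Hochberg over 30 tests, 3 libraries per group). The muscle change was larger by a log2 of 8.40 for Hspa1a (adjusted p = 0.000142), 8.95 for Hspa1b (0.000142), 2.11 for Hspa8 (0.000142) and 3.37 for Dnajb1 (0.0411). It was larger by 3.15 for Hsp90aa1 (0.000515), 2.54 for Bag3 (0.00251), 0.79 for Hspa5 (0.0085) and 5.35 for Atf3 (0.000685) in the same edgeR test with Benjamini-Hochberg adjustment.

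Between species, the change at heat in lung differed (bat minus mouse, log2) for Ahsa2 (-3.10, adjusted p = 0.00494), Zfp184 (1.23), Cmah (1.04), 6330409D20Rik (-3.25) and Fbxw17 (1.08), the last 4 at an adjusted p of 0.0472 (edgeR quasi-likelihood, Benjamini-Hochberg, 3 libraries per group). In muscle it differed for Cox8b (-1.30, adjusted p = 0.0272), Ahsa2 (-1.85, 0.029), Cd209f (2.29, 0.029) and Rbak (0.88, 0.0314) in the same edgeR test with Benjamini-Hochberg adjustment. Of 100 splits of the libraries, 2, the real split among them, gave at least the real 5 genes in lung at heat (highest other 6). In muscle at heat 1, the real split, gave as many as the real 4 (highest other 3). Both shares are under 0.05, without adjustment for the number of comparisons split. They concern the count of genes and do not exclude chance for any single gene. The splits exchanged control and heat labels within each species. Their reference is thus no response in either species, and not a response shared by both. With bat control and recovery labels exchanged, the lung call of Ahsa2 ended (-1.99). At recovery 0 genes were called by edgeR in either tissue (17 in lung and 2 in muscle at an unadjusted p under 0.05, DESeq2 4 and 0). With a real count of 0 all 100 splits must give as many, so they say nothing here (highest other 1 in lung and 3 in muscle).

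In bat lung ENSG00000204389 and ENSG00000204388 were high in control and heat libraries and low at recovery. The shallow library control 3 is argued against, since the log2 change of ENSG00000204389 without it was -6.59 (edgeR with Benjamini-Hochberg adjusted p = 0.0254). Over its alternatives that adjusted p ranged from 3.37e-32 by DESeq2 to 0.176 by edgeR without recovery 1 (Benjamini-Hochberg). An exchange of 1 control with 1 recovery library is argued against as the whole cause, since with any such pair left out the weakest log2 change of either identifier was -6.19 (9 pairs). An exchange of all control and recovery labels cannot be told apart from a real fall (log2 -6.47 for ENSG00000204388), because no marker of condition was fixed for the bat, and a change brought by heat shock and recovery stays open.

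In mouse muscle, B cell and adipocyte markers were high in control 1, control 2 and recovery 1. Whether lymphoid and fat tissue in some libraries brought them stays open, since the B cell sum of recovery 1, 131 times the highest of the other recovery libraries, restates the pattern. Whether a few genes taking most of the counts play a part was not settled. The median B cell change at heat was -3.58 with the dominant gene left out and -3.62 with it. Both were scaled by TMM, which limits the weight of single genes, so leaving that gene out could hardly move the value. An effect of heat shock on these markers cannot be told apart from tissue content at heat, where 10 of 10 B cell markers were lower in every heat library than in every control library.

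In mouse blood, macrophage and fibroblast markers were high in control 3 and heat 2. Macrophages of the serous cavities may be in these libraries: 10 of 12 added markers were higher in both than in the other 4 libraries. Among them Timd4 was at 18.1 and 26.8 CPM and at most 2.13 elsewhere, and Cxcl13 at 8.78 and 13.9 CPM and at most 0.754 elsewhere. For independent genes and 2 libraries taken at random 0.8 would be expected. These 2 libraries were chosen for their high macrophage markers, which vary together, so 0.8 is no fair measure of chance. Whether other macrophages would give as many was not tested. Sex is argued against, since Xist was at 0.092 CPM of total counts in heat 2 and 795 in control 3, and so is heat shock, since the macrophage sum of control 3 was 2.44 times that of control 1 without any heat.

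Within each species and tissue with 3 libraries per group there are 10 splits of 6 libraries, too few for a share under 0.05. The real count and the highest of the other splits were 9 and 0 in bat lung at recovery, 6 and 0 in bat muscle at heat, 426 and 0 in bat muscle at recovery, 1138 and 1 in mouse lung at heat, 6 and 1 in mouse lung at recovery, and 76 and 0 in mouse muscle at heat, with 1 split as large in each. They were 0 and 0 in bat blood at heat and at recovery and in bat lung at heat, with 10 splits as large by edgeR (351, 849 and 1662 genes at an unadjusted p under 0.05, DESeq2 0, 95 and 18). In mouse muscle at recovery 2 splits gave at least the real 12 genes, and the other, which set control 1, control 2 and recovery 1 against the rest, gave 4104 and points to a structure of the samples.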

How the results depend on the processing

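The runs without selected mouse muscle or mouse blood libraries and the exchange of bat labels were chosen after seeing the data, and the other alternatives were set at the start. Values are counts of genes called, with edgeR and Benjamini-Hochberg adjustment unless another tool is named, and the cause of a change was not tested except where fewer libraries or another test make it. Leaving out genes over 5% of counts left each count within 1.5 times the main value. DESeq2's size factors moved 1 count, to 13 in bat muscle at heat. The DESeq2 test gave 95 in bat blood at recovery, 18 and 950 in bat lung at heat and recovery, 778 and 1523 in bat muscle, 519 and 74 in mouse blood, 2156 and 117 in mouse lung, 2362 and 101 in mouse muscle, and 14 and 4 for the species difference in lung. Without a filter on low counts the values were 400 and 18 in mouse blood at heat and recovery, 18 in bat lung at recovery, 22 in mouse lung at recovery, 158 in bat muscle at heat and 228 in mouse muscle at heat. For the species difference they were 1 and 4 in lung at heat and recovery and 0 in muscle at heat (28 at an unadjusted p under 0.05). A log2 change of at least 1 left 340 and 1 in mouse lung at heat and recovery and 256 in bat muscle at recovery. With a block for the replicate number, which the correlations did not show to pair animals outside bat muscle at heat and bat blood at recovery, counts were 0 in bat lung at recovery, 685 and 0 in mouse lung, 63 in bat muscle at heat, 0 and 2 in mouse muscle at heat and recovery, and 1 for the species difference in lung at heat. At an unadjusted p under 0.05 the 3 counts of 0 held 2756, 1265 and 4818 genes. In bat blood at recovery the block gave 0 genes as without it (616 at an unadjusted p under 0.05). With the block 18 of 18 named calls were lost in mouse muscle at heat and 6 of 7 at recovery, where number 3 is the library with high Xist in each condition. In mouse lung, where the same holds for number 3, it ended 16 of 59 at heat and 5 of 5 at recovery. It ended 4 of 4 in bat lung at recovery, 2 of 3 species differences in lung at heat and 0 in bat muscle and in the species difference in muscle. No fold of a named call moved over 1.5 times with the block. Fits of the 2 compared conditions alone gave 1 in mouse blood at recovery, 16 in bat lung at recovery, 331 and 40 in mouse lung, 42 and 95 in bat muscle, and 1130 and 0 in mouse muscle (761 at an unadjusted p under 0.05 at recovery). Exchanging the bat control and recovery labels left 1 species difference in lung at heat. A mean of at least 5 CPM left 1 species difference in muscle at heat. Without mouse blood control 3 and heat 2, counts were 2801 at heat and 992 at recovery, and without mouse muscle control 1, control 2 and recovery 1 they were 0 and 0 (1876 and 1007 at an unadjusted p under 0.05). In these runs control held 1 library in both tissues, and heat held 1 in mouse blood. These counts thus cannot tell the effect of the libraries left out from that of fewer libraries. In the mouse muscle run no fold of a named call moved over 1.5 times, at heat or at recovery. An estimated correlation ended the 5 calls of the heat shock list, with medians of 1.88 and 0.10 in mouse blood at heat and recovery (camera adjusted p = 0.33 and 0.64), 1.92 in lung at heat (0.2), and 1.70 and 1.38 in muscle (0.2 and 0.12).

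With each library left out in turn, counts ranged from 0 to 0 in bat blood at heat and recovery and in bat lung at heat, 0 to 62 in bat lung at recovery, 0 to 104 and 17 to 375 in bat muscle at heat and recovery, 0 to 736 and 0 to 5 in mouse blood, 133 to 2175 and 0 to 62 in mouse lung, and 0 to 2742 and 1 to 45 in mouse muscle. A group of mouse blood then held 1 library, assumed to vary like the other groups. For the species difference they ranged from 1 to 12 and 0 to 3 in lung at heat and recovery, 0 to 7 and 0 to 2 in muscle, and 0 to 0 in blood at both. The heat shock list's median ranged from 1.61 to 2.26 and 0.08 to 0.42 in mouse blood, 1.46 to 2.16 and -0.14 to -0.04 in lung, and 1.44 to 1.93 and 1.19 to 1.64 in muscle. The direction turned for Hspa1a in mouse lung at recovery (-0.55, from -0.80 without control 1 to 0.09 without control 2) and for Fos in mouse muscle at recovery (-0.05, from -0.93 without recovery 2 to 0.27 without control 1, with 0.24 without recovery 1, 0.26 without recovery 3 and 1.09 without control 1, control 2 and recovery 1). Over all values of named genes with 1 library left out, 1004 kept their direction and side of the threshold, 429 lost a call, 48 gained 1 and 4 turned. Total counts were at least 9.29 M. Changes of 2-fold in genes with a mean of at least 5 CPM were recovered in simulated data in 0% of cases in bat blood and 94% in mouse lung. The effect of depth on the counts was not tested.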
